A study of Mus musculus with 16 samples.

How the data were processed

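Messenger RNA of primary mouse CD8+ T cells was sequenced in 16 libraries, 2 for each of 8 retroviral constructs. Per the labels' protocols, cells were lysed in a nucleic acid preservation buffer, and a sequencing service made cDNA and tagmented it. The submitters describe the 2 samples of a group as biological replicates, and what each replicate derives from is not given in the sources used here, so that p-values measure only the spread between these samples. Groups were taken from the sample titles, and no column was left without a sample.

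The deposited table holds estimated counts per gene, which need not be whole, for 45706 Ensembl identifiers, each paired with a symbol. Between 6.74% and 7.28% of a library's values were not whole (tolerance 1e-06), and all were rounded before the count tests. The submitters' processing notes name FastQC 0.12.1, Trim Galore 0.6.7, STAR, Salmon 1.10.1, SAMtools 1.17, Picard 3.0.0, bedtools 2.30.0, featureCounts, Subread 2.0.1, DESeq2 1.40.2 and the mouse genome build GRCm38, with no role or order. The step that made the deposited estimated counts, the annotation and the use of strand are not given in the sources used here. Estimated counts can split reads between genes with shared sequence, and the counts of such genes are uncertain. Library totals were 15051703 to 16659049, the 10 most abundant genes took 10.3% to 12.5% of the counts, and mitochondrial genes took 4.4% to 4.83%.

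Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12894. Counts were normalised by TMM (factors 0.98 to 1.05), and edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was fitted once to all 16 libraries, with the group as the only term and 8 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. The comparisons were WT against EV, each fusion against WT and against EV, FT against the mean of the other 5 fusions, and a test of any difference among the 6 fusions. CPM are counts scaled to the TMM-adjusted library size, by edgeR's definition. A fold against a group with no count was computed against a floor of 3 counts per library, and floors cover counting error only.

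Before the data were examined, 37 gene lists with 631 symbols were fixed, of which 625 were in the table and 532 were tested. The 33 lists with 5 or more tested members were set against all other genes with limma's camera, with a preset correlation of 0.01, and again with an estimated correlation. The number of members past the threshold is given over all genes tested and adjusted over the list alone. Some lists share members.

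The genes named were chosen by a rule fixed before the data were examined. It takes Runx3 and, among genes with an adjusted p below 0.05, a mean of at least 5 CPM in the higher group and both libraries of 1 group above both of the other, those with the largest changes: 12 rises and 12 falls for WT against EV, 8 and 8 for each fusion against WT, 4 and 4 for each fusion against EV, and 6 and 6 for FT against the other fusions. Among the fusions it takes the 10 genes with the smallest p. Genes named Gm and a number, ending in Rik or without a symbol were left out. Called members of the lists are given as examples, smallest adjusted p first, and 16 genes of T cell biology are given for WT against EV whatever the result. Individual levels of B-lineage genes and of Ltb, Prf1, Gzma, Gzme, Gzmd and Irf1 outside these places, and the genes changed in every construct, were chosen after their values were seen.

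Gene positions and overlaps come from the GRCm38 annotation GENCODE M21, which held 45143 of the 45706 identifiers (98.8%). For the 113 named genes, the share of 31-base words that occur in another gene was computed, and 16 shared more than 20% of them, while 7 were overlapped by a gene on the same or the other strand over more than 20% of their exons.

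The steps were tested on simulated counts drawn with the means and library sizes of the real samples. The changed genes were drawn from those with a mean above 1 CPM, so that recovery at lower levels was not tested. In the simulation of WT against EV (12561 genes), 59.7% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold were called, and 12 of 170 calls were false. The simulated FT against EV, in which no gene was changed, gave 1 call.

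The alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter, a filter of 10 counts in 8 libraries, the replicate number as a block, a fit of only the groups compared, and each library left out in turn. Leaving out a library leaves its group with 1 library, which is then assumed to vary like the other groups. A fit without immunoglobulin and J chain genes and counts between pairs of fusions were added after the data were seen. For the shared response, 20 sets of unchanged groups were simulated from the levels of EV, with WT also at those levels for the correlations and at its own for the sign shares. The latter simulation, and a fit with the EV libraries as separate groups, were added after the data were seen. The result of 1 gene is not reported here.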

Results

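RNA sequencing measured the transcriptome of primary mouse CD8+ T cells, the cytotoxic lymphocytes of the adaptive immune system, isolated from the spleen of C57BL/6J mice, activated through CD3 and CD28 and transduced with a retrovirus 16 hours after activation. The virus carried Runx3, a Runt-domain transcription factor that drives the cytotoxic programme of CD8+ T cells, or no insert (empty vector, EV). Runx3 was untagged (WT) or fused to the FlAsH tag (FT), a short peptide that binds a biarsenical dye, to LOV* (LOV), to the engineered ascorbate peroxidase APEX2 (APEX), or to the engineered biotin ligases ultraID (ULTRA), miniTurbo (MINI) or TurboID (TID). Each of the 8 groups had 2 libraries, so that every mean ± SD below has n = 2. The deposited table held 45706 genes, of which 22780 had no count in any library and 12894 passed the filter on low counts. Library totals lay between 15051703 and 16659049 estimated counts, and the biological coefficient of variation was 0.0892. The 2 libraries of a group differed by more than counting noise in all 8 groups (chi-square per degree of freedom 5.8 to 7.85), and their log2 levels correlated across genes with Pearson's r of 0.981 to 0.984. In the following, a change is a log2 fold change ± standard error, positive where the first group named is higher, and a gene counts as changed at an adjusted p below 0.05. Where a group held 1 to 6 counts of a gene in its 2 libraries, the fold is the ratio of counts with its exact binomial interval, which covers counting error only.

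Some of the genes named below share sequence or overlap with a neighbour, and their counts are uncertain to that extent. Of the 31-base words of Pram1, 85.7% also occur in other annotated genes, chiefly in Gm20507, and the shares were 52.3% for Hspb1, 38.2% for Gzmd, 42.1% for Gzme, 22.8% for Gzmf, 33.8% for Gzmg, 57.7% for Khdc1a, 56.6% for Khdc1c, 92.4% for Speer1, 98.5% for Pde2a, 43.1% for Ass1, 33.2% for Ctsd, 39.2% for Akr1c12, 62.9% for Phf11b, 22.6% for Ifng and 27.3% for Serpina3f. Among the list members named, the share was 30% for Me1, 28.5% for Eno1, 57.7% for Ftl1, 51% for Tcrg-C1 and 45.9% for Tcrg-C2. A gene on the same strand covered 99.2% of the exons of Pde2a, 87.5% of Pram1, 34.4% of Ctsd and 25.9% of Ifng. A gene on the opposite strand covered 45.5% of the exons of Gpld1, 23.8% of Adgre5, 21.8% of Tgm2, 18.7% of Xcl1 and 26.5% of Ftl1, and the sources used here do not say whether counting used the strand.

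Of the variance among the 16 libraries, the first principal component held 28.8% and the second 9.5%. On the first component WT lay at 37.7 and 37.6, FT at 35.3 and 35.9, and LOV at 24.4 and 29.2. APEX lay at -7.9 and -8.14 and ULTRA at -5.32 and -11.8, between these and EV at -18.1 and -18.9. MINI, at -31 and -31.5, and TID, at -34.4 and -32.8, lay beyond EV. On the second component the TID libraries lay at -26.6 and -14.5 and those of MINI at -11.4 and -18, so that TID replicate 2 lay nearer to MINI than to TID replicate 1.

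**Figure D1:**
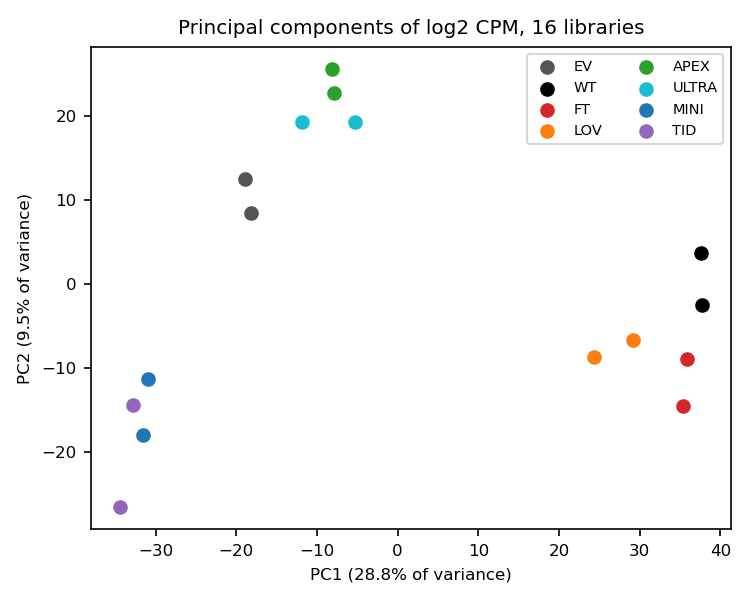
Each point is 1 of the 16 libraries, placed by its first (x axis) and second (y axis) principal component of log2 CPM and coloured by group. WT, FT and LOV lie at 24.4 or more on the first component, and MINI and TID have the lowest values.

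Runx3 itself (chromosome 4, 135120652 to 135177990 of GRCm38, plus strand) was read first in every library. In CPM, counts scaled to library size, EV held 271 and 274, WT 269 and 248, FT 293 and 318, LOV 264 and 277, APEX 222 and 239, MINI 219 and 241, TID 191 and 203, and ULTRA 124 and 129. Against EV, the count did not pass the test in WT (-0.07 ± 0.07, adjusted p = 0.569), FT (0.17 ± 0.07, adjusted p = 0.121) or LOV (-0.01 ± 0.07, adjusted p = 0.965). It was lower than in EV with ULTRA (-1.11 ± 0.07, adjusted p = 1.26e-11) and TID (-0.46 ± 0.07, adjusted p = 4.2e-05). For APEX the change missed the threshold (-0.24 ± 0.07, adjusted p = 0.081) but passed it with DESeq2 (-0.25), with no filter (-0.25) and with a replicate block (-0.24). For MINI it passed (-0.24 ± 0.07, adjusted p = 0.0342), but not when only the compared libraries were fitted (-0.24), nor without EV replicate 1 (-0.26), EV replicate 2 (-0.23) or MINI replicate 1 (-0.18). The sequence of the construct is not given in the sources used here, so that the gene's count does not check the labels.

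**Figure D2:**
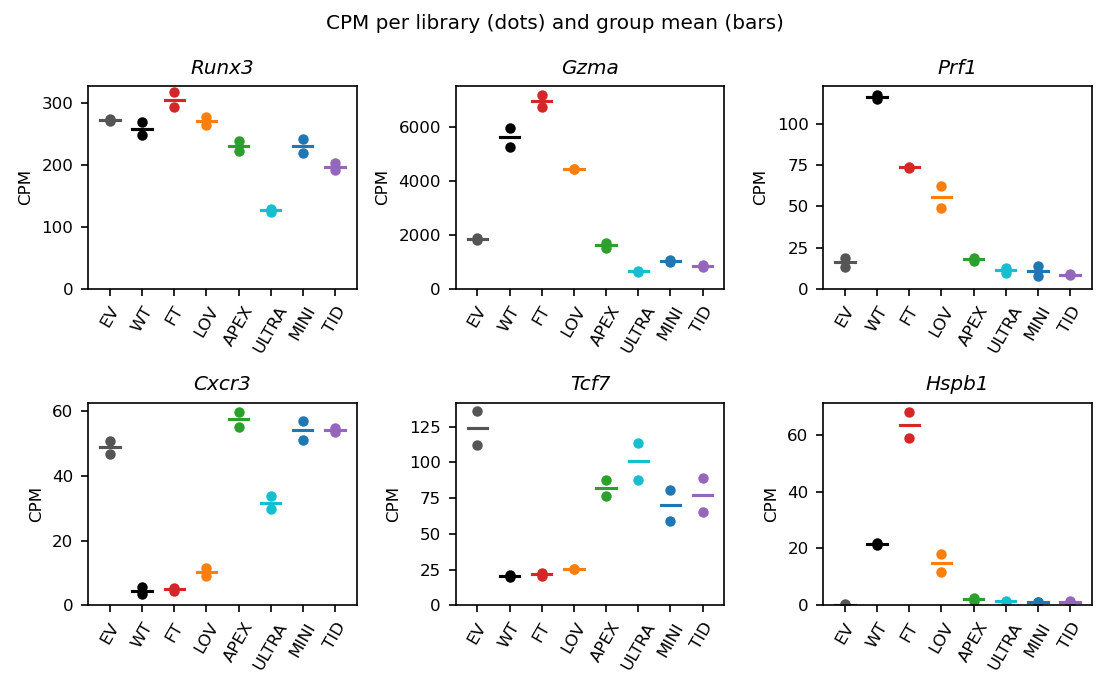
CPM (y axis, linear) of 6 genes in each library (dots) with the mean of each group (bars), groups along the x axis. Gzma and Prf1 are highest in WT, FT and LOV, where Cxcr3 and Tcf7 are lowest, while Runx3 is lowest in ULTRA at 124 and 129 CPM.

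WT against EV compared untagged Runx3 with the empty vector. Several granzyme genes rose. Gzma, which encodes a granule protease of killer cells (chromosome 13, 113093825 to 113100981, minus strand), went from 1833 ± 54.6 to 5599.5 ± 503 CPM (1.61 ± 0.07, adjusted p = 1.04e-15), and Prf1, the pore-forming protein of cytotoxic granules (chromosome 10, 61297833 to 61304680), rose 7.29-fold (2.87 ± 0.22, adjusted p = 3.79e-06). Gzmb, the main apoptosis-inducing granzyme, rose 1.78-fold (0.83 ± 0.07, adjusted p = 5.82e-10), and the clustered granzyme genes Gzmd and Gzme rose 50.5-fold and 40.6-fold, and Gzmg rose as well (52.3-fold, interval 23.8 to 144). Outside the granules, Pram1 had no count in EV and 8.4 ± 0.68 CPM in WT, at least 44.5-fold higher against a floor of 3 counts per library. Hspb1, a small heat shock protein (94.1-fold), Cd300a, an inhibitory receptor (100.3-fold, interval 34 to 489), Yap1, the transcriptional co-activator of the Hippo pathway (93.8-fold, interval 25.6 to 780.4), and Jup, which encodes the junction protein plakoglobin (35.4-fold), rose from low levels in EV. Aoah, an enzyme that inactivates lipopolysaccharide (34.7-fold, interval 15.7 to 95.6), Khdc1a (4.89), Cdc20b (4.83) and Khdc1b (4.73) completed the 12 largest rises.

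Other genes were lower in WT. The chemokine receptor Cxcr3 (chromosome X, 101731535 to 101734269) fell 10.9-fold, from 48.8 ± 2.7 to 4.49 ± 1.52 CPM (-3.44 ± 0.16, adjusted p = 4.76e-15), and Tcf7, the transcription factor TCF-1 of naive and memory T cells (chromosome 11, 52252371 to 52283014), fell 6.12-fold (-2.61 ± 0.21, adjusted p = 1.43e-05). The surface receptor Slamf6 and the scavenger receptors Cd5 and Cd6, which tune T cell receptor signals, changed by -3.72 ± 0.40, -3.64 ± 0.30 and -3.27 ± 0.26. S1pr1, the sphingosine phosphate receptor that lets T cells leave tissue, changed by -2.01 ± 0.30, adjusted p = 0.000274. St6gal1, a sialyltransferase (-4.40), Igfbp4, an insulin-like growth factor binding protein (-3.38), Poglut1 (-3.07), Ctss, the protease cathepsin S (-2.86), Slc14a1, a urea transporter (-2.85), and Pde2a, a phosphodiesterase (-2.73), were also among the 12 largest falls. Jchain, the joining chain of secreted antibodies, led that list (55.1-fold, interval 23.3 to 171, adjusted p = 0.00768), but its call was lost without WT replicate 2 (-4.76). Ighm, the heavy chain of IgM and a marker of B-lineage cells, stood at 159 ± 7.01 CPM in EV and 62.8 ± 9.32 in WT (-1.34 ± 0.21, adjusted p = 0.00298).

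By the gene lists fixed before the data were examined, the genes of cytotoxic granules rose together: 14 were higher and 0 lower of 21 tested. With 14 and 0 adjusted over the list alone, camera gave adjusted p = 5.64e-16, and adjusted p = 0.0124 with an estimated correlation. Of the list of effector genes that Runx3 is known to activate, which shares members with it, 11 were higher and 0 lower of 20 tested, with the chemokine genes Ccl4 (2.42 ± 0.25) and Ccl3 (30.8-fold, interval 11.7 to 115) among them. With 12 and 1 adjusted over the list alone, camera gave adjusted p = 1.03e-08, and adjusted p = 0.0124 with an estimated correlation. Genes of the oxidative stress response driven by NRF2 rose as well: 9 were higher and 0 lower of 23 tested. With 11 and 0 adjusted over the list alone, camera gave adjusted p = 4.48e-07, and adjusted p = 0.0124 with an estimated correlation. These were led by Me1, malic enzyme (4.07 ± 0.36), and the ferritin chains Fth1 (0.67 ± 0.07) and Ftl1 (1.00 ± 0.09). Of the genes of circulating T cells that leave tissue, 1 was higher and 11 lower of 24 tested, among them Atp1b3, a sodium pump subunit (-0.45), and the lymph node homing receptor Ccr7 (-2.46). With 2 and 14 adjusted over the list alone, camera gave adjusted p = 4.48e-07, and adjusted p = 0.0124 with an estimated correlation. Integrins and chemokine receptors overlapped with these: 2 were higher and 11 lower of 21 tested. With 2 and 11 adjusted over the list alone, camera gave adjusted p = 3.64e-05, and adjusted p = 0.0124 with an estimated correlation. In the list of naive and memory genes, led by the cytokine Ltb (-1.54 ± 0.09), 2 were higher and 8 lower of 20 tested. With 2 and 11 adjusted over the list alone, camera gave adjusted p = 3.09e-06, and adjusted p = 0.0707 with an estimated correlation.

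Further groups changed as well. Of the endoplasmic reticulum and unfolded protein genes, 9 were higher and 1 lower of 20 tested, led by Creld2 (0.87) and Sdf2l1 (0.51). With 13 and 1 adjusted over the list alone, camera gave adjusted p = 3.09e-06, and adjusted p = 0.189 with an estimated correlation. Of the genes of the G2 and M phases of the cell cycle, 0 were higher and 9 lower of 30 tested, and topoisomerase Top2a changed most clearly (-0.43). With 0 and 11 adjusted over the list alone, camera gave adjusted p = 8.29e-05, and adjusted p = 0.0894 with an estimated correlation. Type I interferon genes followed: 6 were higher and 1 lower of 23 tested, led by the nucleic acid sensor Zbp1 (1.02). With 9 and 1 adjusted over the list alone, camera gave adjusted p = 0.0024, and adjusted p = 0.407 with an estimated correlation. S phase genes (1 up and 6 down of 28, or 1 and 8 adjusted over the list alone) had an adjusted p = 0.00503, and adjusted p = 0.407 with an estimated correlation. That call was lost without EV replicate 2 (adjusted p = 0.113) and without WT replicate 1 (adjusted p = 0.0654). Markers of other lymphocytes moved too. Of the markers of gamma-delta T cells, 0 were higher and 3 lower of 5 tested, with the gamma chain constant genes Tcrg-C1 (-2.28 ± 0.13) and Tcrg-C2 (-1.76 ± 0.29). With 0 and 4 adjusted over the list alone, camera gave adjusted p = 2.11e-06, and adjusted p = 0.0224 with an estimated correlation. Of the markers of natural killer and innate-like cells, 4 were higher and 1 lower of 5 tested, with the signalling adaptor Fcer1g at 22 ± 7.59 CPM in EV and 247 ± 32.1 in WT (3.49 ± 0.29). With 4 and 1 adjusted over the list alone, camera gave adjusted p = 0.000605, and adjusted p = 0.0894 with an estimated correlation.

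Several T cell genes fixed before the data were examined did not pass the test. Runx1 (-0.56, adjusted p = 0.146) and Runx2 (-0.16, adjusted p = 0.371), the other Runx factors, Cd8a, the CD8 alpha chain (-0.20, adjusted p = 0.187), Ifng, interferon gamma (0.51, adjusted p = 0.655), Klf2 (-0.37, adjusted p = 0.0837), Cd69 (-0.22, adjusted p = 0.0784) and the integrin gene Itgae, at 1.07 ± 0.617 CPM in EV (-1.34, adjusted p = 0.343), are given as values. Cd8a passed with no filter (-0.21), without EV replicate 1 (-0.34) and without WT replicate 2 (-0.37), and Klf2 with no filter (-0.38), a replicate block (-0.37), only EV and WT fitted (-0.37) and without EV replicate 1 (-0.55). Cd4 did not pass the filter on low counts. The transcription factor gene Tbx21, or T-bet, rose (0.75 ± 0.11, adjusted p = 1.9e-05). Cbfb, the partner of Runx proteins (-0.20 ± 0.07, adjusted p = 0.0425), and Eomes, the second T-box factor of effector cells (0.26 ± 0.07, adjusted p = 0.0153), passed. Cbfb lost its call without EV replicate 2 (-0.15), WT replicate 1 (-0.19) or WT replicate 2 (-0.22), with no filter (-0.20) and when only EV and WT were fitted (-0.20), and Eomes without EV replicate 2 (0.20), WT replicate 1 (0.26) or WT replicate 2 (0.25).

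In all, 1802 of 12894 genes changed in WT against EV by edgeR's quasi-likelihood test, 879 higher and 923 lower, and 269 and 231 of these by more than 2-fold. Without EV replicate 2 the number was 1128, and without WT replicate 2 it was 1061.

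**Figure D3:**
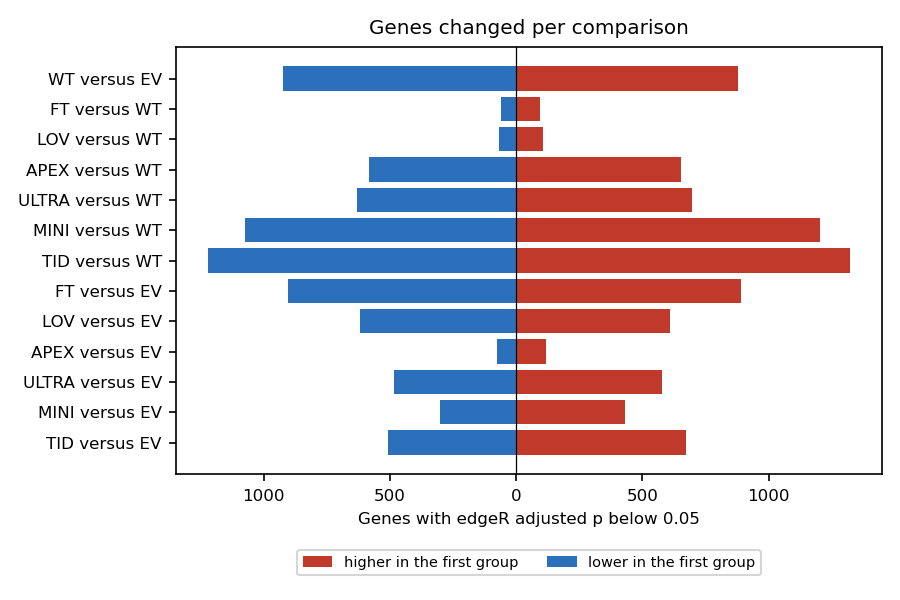
Number of genes with an edgeR adjusted p below 0.05 (x axis, genes) in each comparison (y axis), with genes higher in the first group to the right and lower to the left. Against WT the number is 152 for FT and 176 for LOV, and 2540 for TID.

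**Figure D4:**
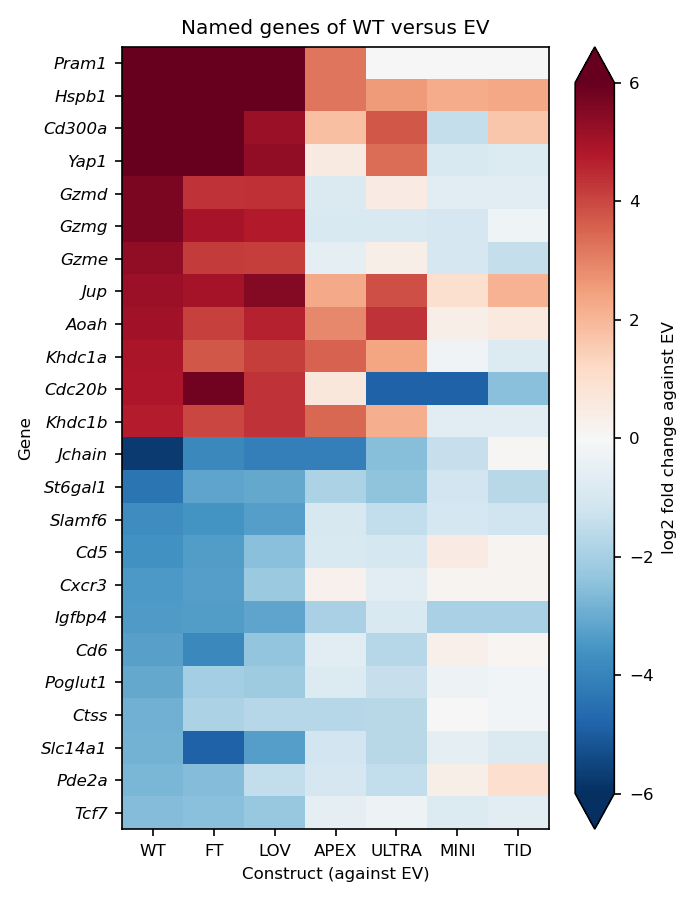
Log2 fold change against EV (colour, saturated beyond 6 in either direction) of the 24 genes with the largest changes in WT (y axis) in each of the 7 constructs (x axis). FT and LOV have the sign of WT in all of these genes, while the fitted sign is opposite to WT in 4 genes in APEX, 2 in ULTRA, 12 in MINI and 12 in TID, and Pram1 had no count in EV, ULTRA, MINI or TID.

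FT against WT asks what the FlAsH tag added to or took from the effect of Runx3. Few genes differed. Mpp2, a membrane scaffold protein (chromosome 11, 102057015 to 102088515), was 3.13-fold higher in FT (1.65 ± 0.21, adjusted p = 2.99e-05), Hspb1 (chromosome 5, 135887919 to 135889563) was 2.96-fold higher (1.57 ± 0.20, adjusted p = 6.82e-05), and Phf11b was 2.44-fold higher (1.29 ± 0.17, adjusted p = 3.18e-05). Gem, a small GTPase (chromosome 4, 11704457 to 11714752), was 2.5-fold lower, at 82.8 ± 14.2 against 207 ± 16.7 CPM (-1.32 ± 0.11, adjusted p = 2.2e-07), and Irf8, a transcription factor of the interferon regulatory family (chromosome 8, 120736358 to 120756694), was 2.35-fold lower (-1.23 ± 0.10, adjusted p = 7.13e-07). Tuba8, an alpha tubulin, was lower too (-1.27 ± 0.22, adjusted p = 0.00122). Frat2 (1.52 ± 0.38), Stx1a (1.46 ± 0.29), Fam46c (1.26 ± 0.31), Rap1gap2 (1.20 ± 0.30) and Plxnc1 (1.20 ± 0.25) were also among the largest rises, and Zic5 (-2.20 ± 0.55), Cdh17 (-1.92 ± 0.41), Gcnt4 (-1.37 ± 0.28), Wdr95 (-1.30 ± 0.25) and Cuedc1 (-1.18 ± 0.30) among the largest falls, but each of these lost its call in at least 1 other fit. Without WT replicate 1, the call was lost for Frat2 (1.20), Stx1a (1.41), Fam46c (1.21), Rap1gap2 (1.07), Zic5 (-2.21), Cdh17 (-2.03), Gcnt4 (-1.18), Wdr95 (-1.33) and Cuedc1 (-0.87). Without WT replicate 2, the call was lost for Frat2 (1.92), Stx1a (1.52), Fam46c (1.31), Rap1gap2 (1.35), Plxnc1 (0.87), Zic5 (-2.19), Cdh17 (-1.80), Wdr95 (-1.26) and Cuedc1 (-1.43). Without FT replicate 1, the call was lost for Frat2 (1.72), Fam46c (1.07), Rap1gap2 (1.24), Plxnc1 (0.99), Zic5 (-1.85), Cdh17 (-1.85), Gcnt4 (-1.03) and Cuedc1 (-1.06). Without FT replicate 2, the call was lost for Frat2 (1.28), Stx1a (1.35), Fam46c (1.43), Rap1gap2 (1.174), Zic5 (-2.66), Cdh17 (-1.99), Wdr95 (-0.91) and Cuedc1 (-1.29). With only the compared libraries fitted, the call was lost for Cuedc1 (-1.18). With DESeq2, the call was lost for Frat2 (1.52), Fam46c (1.26), Rap1gap2 (1.20) and Cuedc1 (-1.18).

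In the lists, cholesterol synthesis genes were higher in FT than in WT: 4 were higher and 0 lower of 20 tested, led by squalene synthase Fdft1 (0.49 ± 0.09). With 9 and 0 adjusted over the list alone, camera gave adjusted p = 6.81e-13, and adjusted p = 0.0551 with an estimated correlation. Of the Myc and ribosome biogenesis genes, 0 were higher and 1 lower of 24 tested. With 0 and 7 adjusted over the list alone, camera gave adjusted p = 8.44e-10, and adjusted p = 0.191 with an estimated correlation. Of the markers of natural killer and innate-like cells, 0 were higher and 1 lower of 5 tested, with Eomes (-0.51 ± 0.07, adjusted p = 0.000141) as the member that fell. With 0 and 4 adjusted over the list alone, camera gave adjusted p = 9.33e-07, and adjusted p = 0.0551 with an estimated correlation. No list held its call with an estimated correlation. In all, 152 genes differed by edgeR's quasi-likelihood test, 94 higher and 58 lower, against 1802 between WT and EV. The number was 54 without WT replicate 1, 65 without WT replicate 2, 58 without FT replicate 1, 90 without FT replicate 2 and 288 with no filter on low counts.

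LOV against WT also gave few calls, with 1652 genes at an unadjusted p below 0.05 by edgeR's test, where 644.7 are expected with no difference. Cdh17, a cadherin of intestinal epithelium and some lymphocytes (chromosome 4, 11758147 to 11817895), was 8.21-fold lower in LOV, at 0.947 ± 0.128 against 7.83 ± 0.858 CPM (-3.04 ± 0.44, adjusted p = 0.000387), and Gem was 2.41-fold lower (-1.27 ± 0.11, adjusted p = 4.56e-07). Ltb, the cytokine lymphotoxin beta, was higher (0.67 ± 0.09, adjusted p = 9.44e-05). Cxcr3 was 2.3-fold higher (1.20 ± 0.18, adjusted p = 0.000707), but lost the call without WT replicate 2 (0.90). RP24-559G13.2 (1.67 ± 0.34), Zcchc24 (1.27 ± 0.31), Abca3 (1.20 ± 0.26), Klhl30 (1.18 ± 0.27), Ctss (1.15 ± 0.27), RP24-328P2.5 (1.13 ± 0.27) and Tmem71 (1.06 ± 0.24) were also among the largest rises, and Tgm2 (-1.99 ± 0.41), Sept8 (-1.28 ± 0.32), Nrgn (-1.21 ± 0.22), Gzme (-1.20 ± 0.23), Adamts14 (-1.19 ± 0.25) and Tuba8 (-1.09 ± 0.21) among the largest falls, but each of these lost its call in at least 1 other fit. Without WT replicate 1, the call was lost for RP24-559G13.2 (1.61), Zcchc24 (1.29), Klhl30 (1.25), Ctss (1.07), RP24-328P2.5 (1.13), Tmem71 (1.07), Sept8 (-1.03), Nrgn (-0.99), Gzme (-1.23) and Adamts14 (-1.13). Without WT replicate 2, the call was lost for RP24-559G13.2 (1.73), Zcchc24 (1.26), Abca3 (0.97), Klhl30 (1.11), Ctss (1.24), RP24-328P2.5 (1.14), Tmem71 (1.06), Tgm2 (-1.68), Sept8 (-1.49), Gzme (-1.16), Adamts14 (-1.23) and Tuba8 (-1.04). Without LOV replicate 1, the call was lost for RP24-559G13.2 (1.72), Zcchc24 (1.27), Klhl30 (1.03), RP24-328P2.5 (1.09), Tmem71 (0.93), Tgm2 (-1.77), Sept8 (-1.40), Gzme (-0.95), Adamts14 (-1.07) and Tuba8 (-1.11). Without LOV replicate 2, the call was lost for RP24-559G13.2 (1.62), Zcchc24 (1.28), Abca3 (0.90), Klhl30 (1.31), Ctss (0.82), RP24-328P2.5 (1.172), Tmem71 (1.18), Tgm2 (-2.23), Sept8 (-1.17), Nrgn (-1.04), Adamts14 (-1.31) and Tuba8 (-1.07). With only the compared libraries fitted, the call was lost for Abca3 (1.20) and Ctss (1.15). With DESeq2, the call was lost for Gzme (-1.20).

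Of the endoplasmic reticulum and unfolded protein genes, 0 were higher and 2 lower of 20 tested (0 and 10 adjusted over the list alone, camera adjusted p = 4.43e-09, adjusted p = 0.215 with an estimated correlation), and of the Myc and ribosome biogenesis genes, 0 were higher and 2 lower of 24 tested (0 and 10 adjusted over the list alone, camera adjusted p = 1.85e-08, adjusted p = 0.215 with an estimated correlation). Of the NRF2 genes, 0 were higher and 2 lower of 23 tested. With 0 and 6 adjusted over the list alone, camera gave adjusted p = 1.05e-05, and adjusted p = 0.0404 with an estimated correlation. Cytotoxic granule genes differed in both directions: 1 was higher and 3 lower of 21 tested. With 3 and 4 adjusted over the list alone, camera gave adjusted p = 0.00506, and adjusted p = 0.315 with an estimated correlation. In all, 176 genes differed by edgeR's test, 107 higher and 69 lower. The number was 13 without WT replicate 2, 40 without LOV replicate 1, 43 without LOV replicate 2 and 366 with no filter on low counts.

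In APEX against WT, Cxcr3 was 12.8-fold higher, at 57.6 ± 3.28 against 4.49 ± 1.52 CPM (3.68 ± 0.16, adjusted p = 7.32e-16). Slamf6 (2.74 ± 0.41), Cd5 (2.73 ± 0.31), Cd6 (2.59 ± 0.26) and Cd226, an activating receptor of T and natural killer cells (2.44 ± 0.25), were higher, as were the serpin gene Serpina3f (2.50), the retinoid receptor gene Rxra (2.35) and Dnajc27 (2.25). Gzmd was 92.5-fold lower (-6.53 ± 0.46, adjusted p = 3.72e-05), and Gzme 59.7-fold. Gzmf (48.2-fold, interval 18.5 to 179), Pram1 (131-fold, interval 35.9 to 1087), Gzmg (103-fold, interval 34.8 to 500.3), Yap1 (61.3-fold, interval 20.6 to 300), Cd300a (-4.72) and Speer1 (-4.21) were lower.

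Of the cytotoxic granule genes, 1 was higher and 11 lower of 21 tested, with Gzma at -1.81 ± 0.07 and Prf1 at -2.70 ± 0.22. With 3 and 13 adjusted over the list alone, camera gave adjusted p = 9.66e-12, and adjusted p = 0.0273 with an estimated correlation. Interferon gamma response and antigen presentation genes were higher: 13 were higher and 0 lower of 25 tested, led by the immunity-related GTPase Irgm2 (0.97 ± 0.14) and the guanylate binding protein Gbp7 (0.51 ± 0.08). With 17 and 0 adjusted over the list alone, camera gave adjusted p = 9.47e-15, and adjusted p = 0.0116 with an estimated correlation. Of the NRF2 genes, 0 were higher and 9 lower of 23 tested (1 and 9 adjusted over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.0273 with an estimated correlation), and of the genes of circulating T cells, 9 were higher and 2 lower of 24 tested (11 and 3 adjusted over the list alone, camera adjusted p = 5.44e-05, adjusted p = 0.0293 with an estimated correlation). For the endoplasmic reticulum genes, 1 was higher and 8 lower of 20 tested. With 1 and 11 adjusted over the list alone, camera gave adjusted p = 1.1e-07, and adjusted p = 0.119 with an estimated correlation. Of the gamma-delta T cell markers, 2 were higher and 0 lower of 5 tested, and Ighm stood at 94.1 ± 12.8 CPM. With 2 and 0 adjusted over the list alone, camera gave adjusted p = 0.00327, and adjusted p = 0.119 with an estimated correlation. In all, 1237 genes differed by edgeR's test, 655 higher and 582 lower. The number was 729 without WT replicate 2, 709 without APEX replicate 1 and 755 without APEX replicate 2.

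In ULTRA against WT, the chemokine gene Xcl1 was 13.5-fold higher, at 38.9 ± 2.43 against 2.88 ± 0.438 CPM (3.75 ± 0.29, adjusted p = 1.61e-09), and Cxcr3 (2.82 ± 0.16), Tnfsf8, or CD30 ligand (2.64 ± 0.16), Tmem176b (2.60), Cxxc5 (2.59), Cd5 (2.56), Cd226 (2.47) and Igfbp4 (2.46) were higher. Gzma changed by -3.12 ± 0.08 (adjusted p = 5.94e-23), at 645 ± 23.2 CPM. Pram1 and Cdc20b had no count in ULTRA and were at least 44.1-fold and 34-fold lower, and Gzmg (104-fold, interval 35.1 to 505), Gzme (-4.98), Man1c1, a mannosidase (56.1-fold, interval 18.9 to 275), Gpx8, a peroxidase of the endoplasmic reticulum (-5.24), and Zcchc14 (-4.29) were lower. Gzmd was lower (-5.18 ± 0.41, adjusted p = 6.69e-05) but lost the call when only the compared libraries were fitted (-5.18).

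Of the interferon gamma and antigen presentation genes, 14 were higher and 0 lower of 25 tested, with Irgm2 (0.95) and Irf1 (0.55) leading. With 18 and 0 adjusted over the list alone, camera gave adjusted p = 7.81e-17, and adjusted p = 0.00744 with an estimated correlation. Of the cytotoxic granule genes, 1 was higher and 12 lower of 21 tested. With 4 and 13 adjusted over the list alone, camera gave adjusted p = 6.4e-11, and adjusted p = 0.0535 with an estimated correlation. Glycolysis and hypoxia genes fell: 0 were higher and 11 lower of 24 tested, among them the prolyl hydroxylase P4ha1 (-1.03 ± 0.10) and the growth factor Vegfa (-1.88 ± 0.23). With 0 and 15 adjusted over the list alone, camera gave adjusted p = 2.47e-10, and adjusted p = 0.122 with an estimated correlation. Amino acid stress genes driven by ATF4 fell too: 0 were higher and 14 lower of 22 tested, led by asparagine synthetase Asns (-1.09 ± 0.11). With 0 and 17 adjusted over the list alone, camera gave adjusted p = 1.84e-10, and adjusted p = 0.122 with an estimated correlation. Of the cholesterol synthesis genes, 6 were higher and 0 lower of 20 tested. With 8 and 0 adjusted over the list alone, camera gave adjusted p = 9e-06, and adjusted p = 0.122 with an estimated correlation. Of the gamma-delta T cell markers, 2 were higher and 0 lower of 5 tested, and Ighm stood at 82.4 ± 0.348 CPM. With 3 and 0 adjusted over the list alone, camera gave adjusted p = 8.1e-05, and adjusted p = 0.0867 with an estimated correlation. In all, 1324 genes differed by edgeR's test, 695 higher and 629 lower. The number was 851 without WT replicate 1, 874 without WT replicate 2 and 768 without ULTRA replicate 2.

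MINI against WT differed in more genes. Morc1, a germline chromatin protein (chromosome 16, 48431237 to 48630900), was 27.7-fold higher (4.79 ± 0.54, adjusted p = 6.22e-06), Cd5 17.3-fold (4.11 ± 0.30, adjusted p = 5.27e-07), Cxcr3 12-fold (3.59 ± 0.16, adjusted p = 1.41e-15) and the paired membrane protein genes Tmem176b and Tmem176a 16.7-fold and 14.8-fold. Gpld1, a phospholipase (4.10), and Pacsin1 (3.90) were higher, and Akr1c12 (3.73) was higher but lost the call without WT replicate 1 (3.47) or WT replicate 2 (4.06). Pram1 and Cdc20b had no count in MINI and were at least 46.2-fold and 35.6-fold lower. Gzme was 80.7-fold lower and Gzmd 77.3-fold, and Cd300a (312-fold, interval 55.6 to 12370), Yap1 (195-fold, interval 34.5 to 7734), Gzmg (109-fold, interval 36.8 to 529.8) and Dixdc1 (63.2-fold, interval 21.3 to 309) were lower.

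Of the cytotoxic granule genes, 0 were higher and 14 lower of 21 tested, with Gzma at -2.44 ± 0.07. With 1 and 14 adjusted over the list alone, camera gave adjusted p = 2.69e-12, and adjusted p = 0.0239 with an estimated correlation. Of the genes of circulating T cells, 14 were higher and 1 lower of 24 tested (15 and 1 adjusted over the list alone, camera adjusted p = 1.81e-06, adjusted p = 0.0239 with an estimated correlation), and of the naive and memory genes, 12 were higher and 1 lower of 20 tested (12 and 1 adjusted over the list alone, camera adjusted p = 4.04e-06, adjusted p = 0.0578 with an estimated correlation). Of the NRF2 genes, 1 was higher and 10 lower of 23 tested. With 3 and 12 adjusted over the list alone, camera gave adjusted p = 4.71e-05, and adjusted p = 0.0239 with an estimated correlation. Cholesterol synthesis genes were lower in MINI: 0 were higher and 11 lower of 20 tested, led by Hmgcs1 of the mevalonate pathway (-0.69 ± 0.07). With 0 and 15 adjusted over the list alone, camera gave adjusted p = 4.27e-08, and adjusted p = 0.0578 with an estimated correlation. Of the ATF4 genes, 0 were higher and 12 lower of 22 tested. With 0 and 16 adjusted over the list alone, camera gave adjusted p = 4.27e-08, and adjusted p = 0.0833 with an estimated correlation. Interferon gamma and antigen presentation genes were higher: 10 were higher and 1 lower of 25 tested, with the class I light chain B2m at 0.36 ± 0.07. With 13 and 1 adjusted over the list alone, camera gave adjusted p = 4.51e-06, and adjusted p = 0.0503 with an estimated correlation. Beside these, Ighm stood at 247 ± 53.2 CPM (1.98 ± 0.21, adjusted p = 0.000203), the B cell receptor chain Cd79b changed by 1.63 ± 0.28, and of the gamma-delta T cell markers, 2 were higher and 0 lower of 5 tested. With 3 and 0 adjusted over the list alone, camera gave adjusted p = 0.000194, and adjusted p = 0.0578 with an estimated correlation. In all, 2278 genes differed by edgeR's test, 1203 higher and 1075 lower, or 1512 in total without MINI replicate 2.

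TID against WT gave the largest number of genes of the 6 comparisons with WT. Pdgfb, a growth factor chain, was higher (45.8-fold, interval 17.6 to 169.9, adjusted p = 2.46e-07), as were Alox5ap, the activating protein of leukotriene synthesis (32.9-fold, interval 13.8 to 103, adjusted p = 3.69e-06), and Morc1 (40.5-fold, 5.34 ± 0.53, adjusted p = 1.45e-06), and Gpld1 (4.36), Tmem176a (4.08) and Tmem176b (3.99) were higher. Igha, the heavy chain of IgA, stood at 7.3 ± 3.49 against 0.45 ± 0.274 CPM (3.998 ± 0.76, adjusted p = 0.00142), Ighm at 282 ± 62.2 against 62.8 ± 9.32 CPM (2.17 ± 0.21, adjusted p = 9.95e-05) and Jchain at 9.17 ± 7.1 CPM (56.5-fold, interval 23.9 to 175, adjusted p = 0.00505), whose call was lost when only the compared libraries were fitted (fitted log2 value 5.77). Pram1 had no count in TID and was at least 44.1-fold lower. Gzme was 109.7-fold lower, Gzmd 78.2-fold and Khdc1a 52.8-fold, and Cdc20b (204-fold, interval 36.2 to 8095), Yap1 (186-fold, interval 32.9 to 7377), Zcchc14 (-5.90) and Gzmg (62.2-fold, interval 26.4 to 193) were lower.

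Of the cytotoxic granule genes, 1 was higher and 13 lower of 21 tested, with Gzma at -2.71 ± 0.07. With 1 and 14 adjusted over the list alone, camera gave adjusted p = 1.44e-12, and adjusted p = 0.0337 with an estimated correlation. Cholesterol synthesis genes were lower: 0 were higher and 14 lower of 20 tested, with Hmgcs1 at -0.84 ± 0.07 and lanosterol synthase Lss at -0.86 ± 0.12. With 0 and 15 adjusted over the list alone, camera gave adjusted p = 2.1e-09, and adjusted p = 0.0496 with an estimated correlation. Of the ATF4 genes, 0 were higher and 14 lower of 22 tested (0 and 15 adjusted over the list alone, camera adjusted p = 2.22e-09, adjusted p = 0.0677 with an estimated correlation), and of the heat shock genes, 0 were higher and 9 lower of 17 tested (0 and 10 adjusted over the list alone, camera adjusted p = 1.12e-05, adjusted p = 0.0496 with an estimated correlation). Of the NRF2 genes, 1 was higher and 10 lower of 23 tested (3 and 12 adjusted over the list alone, camera adjusted p = 8.64e-05, adjusted p = 0.0337 with an estimated correlation), and of the genes of circulating T cells, 15 were higher and 3 lower of 24 tested (16 and 3 adjusted over the list alone, camera adjusted p = 2.52e-05, adjusted p = 0.0385 with an estimated correlation). Of the interferon gamma and antigen presentation genes, 11 were higher and 0 lower of 25 tested. With 14 and 0 adjusted over the list alone, camera gave adjusted p = 1.37e-06, and adjusted p = 0.0394 with an estimated correlation. Of the gamma-delta T cell markers, 2 were higher and 0 lower of 5 tested. With 3 and 0 adjusted over the list alone, camera gave adjusted p = 0.000107, and adjusted p = 0.0496 with an estimated correlation. In all, 2540 genes differed by edgeR's test, 1322 higher and 1218 lower, or 1692 in total without TID replicate 1.

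Each fusion was also set against EV, which asks what the tagged protein changed over the background of transduction. Pram1 and Hspb1 rose in FT and LOV, and Slamf6 and Slc14a1 fell. Pram1 was at least 83.4-fold higher in FT and at least 42.3-fold higher in LOV, and Hspb1 rose 279-fold (8.12 ± 0.35, adjusted p = 7.17e-14) and 64.8-fold (6.02 ± 0.39, adjusted p = 1.91e-10). In FT, Yap1 (145-fold, interval 39.8 to 1204) and Cd300a (71.7-fold, interval 24.2 to 350.3) rose, and Slc14a1 (-4.83), Cd6 (-3.89) and Slamf6 (-3.61) fell. Jchain fell in FT as well (-3.89) but lost the call without EV replicate 1 (-3.03), FT replicate 1 (-4.51) or FT replicate 2 (-3.47). In LOV, Gzmg (28.5-fold, interval 12.8 to 78.8) and Jup (5.49, lost with only LOV and EV fitted at 5.49) rose and Slamf6 (-3.31) and Slc14a1 (-3.30) fell. Jchain (-4.12) lost its call without LOV replicate 1 (-4.74) or replicate 2 (-3.71), and Slc15a1, a peptide transporter (-3.88), without LOV replicate 1 (-3.26). Of the cytotoxic granule genes in FT, 13 were higher and 1 lower of 21 tested (15 and 1 adjusted over the list alone, camera adjusted p = 1.09e-14, adjusted p = 0.0176 with an estimated correlation), and in LOV, 14 were higher and 0 lower of 21 tested (14 and 0 adjusted over the list alone, camera adjusted p = 1.13e-20, adjusted p = 0.0183 with an estimated correlation). Cholesterol synthesis genes rose in FT: 10 were higher and 0 lower of 20 tested. With 13 and 0 adjusted over the list alone, camera gave adjusted p = 6.75e-09, and adjusted p = 0.0764 with an estimated correlation. In all, 1795 genes changed in FT (892 higher, 903 lower), 1078 without EV replicate 2 and 1100 without FT replicate 1. In LOV, 1227 changed (610 higher, 617 lower), 654 without EV replicate 2, 817 without LOV replicate 1 and 583 without LOV replicate 2.

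APEX changed few genes against EV. Khdc1c and Khdc1b rose 12-fold (3.59 ± 0.21, adjusted p = 9.86e-08) and 11-fold (3.46 ± 0.30, adjusted p = 3.71e-08), and Nrgn, neurogranin, rose by 2.68. Khdc1a rose too (3.52), a call lost with only APEX and EV fitted (3.52). Igfbp4 (-1.94 ± 0.23, adjusted p = 1.26e-05), Ctss (-1.70) and Arfgef3 (-1.58) fell. Ptprk, a receptor phosphatase (-1.93), lost its call without EV replicate 1 (-1.61), EV replicate 2 (-2.20), APEX replicate 1 (-2.23) or APEX replicate 2 (-1.68). Of the interferon gamma and antigen presentation genes, 13 were higher and 0 lower of 25 tested, with the guanylate binding protein Gbp7 at 0.58 ± 0.08 and the peptide transporter Tap1 at 0.42 ± 0.07. With 21 and 0 adjusted over the list alone, camera gave adjusted p = 3.23e-35, and adjusted p = 0.000609 with an estimated correlation. In all, 192 genes changed, 117 higher and 75 lower. The number was 96 without EV replicate 2, 124 without APEX replicate 1, 91 without APEX replicate 2 and 320 with no filter.

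In ULTRA against EV, Fads3, a fatty acid desaturase, rose 11.2-fold (3.49 ± 0.28, adjusted p = 2.61e-09), Cd63, a tetraspanin of lysosomes and granules, 10.4-fold (3.38 ± 0.30, adjusted p = 1.34e-08), and Jup (3.88) and Xcl1 (2.96) rose. Ptprk (-2.73), the adenylate kinase Ak4 (-2.52) and the adhesion receptor Adgre5, or CD97 (-2.36), fell. St6gal1 (-2.41) lost its call with no filter (-2.41) and without EV replicate 1 (-2.26), EV replicate 2 (-2.55), ULTRA replicate 1 (-2.93) or ULTRA replicate 2 (-2.02). Of the interferon gamma and antigen presentation genes, 17 were higher and 0 lower of 25 tested. With 23 and 0 adjusted over the list alone, camera gave adjusted p = 7.77e-25, and adjusted p = 0.00184 with an estimated correlation. Of the NRF2 genes, 9 were higher and 0 lower of 23 tested. With 10 and 0 adjusted over the list alone, camera gave adjusted p = 2.73e-08, and adjusted p = 0.0061 with an estimated correlation. Glycolysis and hypoxia genes fell: 0 were higher and 13 lower of 24 tested (0 and 19 adjusted over the list alone, camera adjusted p = 9.8e-18, adjusted p = 0.0673 with an estimated correlation), and cholesterol synthesis genes rose: 12 were higher and 0 lower of 20 tested (13 and 0 adjusted over the list alone, camera adjusted p = 6.25e-11, adjusted p = 0.0673 with an estimated correlation). In all, 1063 genes changed, 579 higher and 484 lower. The number was 657 without EV replicate 1, 565 without EV replicate 2, 576 without ULTRA replicate 1 and 650 without ULTRA replicate 2.

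Against EV, Igfbp4 and Dab2ip fell in both MINI and TID. In MINI, Tmem176b (2.09 ± 0.25, adjusted p = 2.04e-06), Epcam, an epithelial adhesion molecule (2.000), and Ccl4 (1.92) rose, and Tmem121 (-2.23), Igfbp4 (-1.94) and Dab2ip (-1.78) fell. In TID, Igha (5.00 ± 0.84, adjusted p = 0.00147) and Alox5ap (3.20) rose, and Endou (-2.005), Igfbp4 (-1.94), Piwil4 (-1.88) and Dab2ip (-1.88) fell. The connexin gene Gja5 was higher in MINI (2.89) and TID (3.41) but lost both calls without EV replicate 1 (2.97 and 3.49) or EV replicate 2 (2.81 and 3.33), and in MINI also without MINI replicate 1 (2.71) or MINI replicate 2 (3.04). Slc15a1 in MINI (-2.56) lost its call without EV replicate 2 (-1.81), MINI replicate 1 (-2.88) or MINI replicate 2 (-2.30), and Akr1c12 in TID (2.44) without EV replicate 1 (2.50), EV replicate 2 (2.37) or TID replicate 1 (1.74). Of the interferon gamma and antigen presentation genes in MINI, 11 were higher and 0 lower of 25 tested (16 and 0 adjusted over the list alone, camera adjusted p = 3.57e-17, adjusted p = 0.00729 with an estimated correlation), and in TID, 15 were higher and 0 lower of 25 tested (18 and 0 adjusted over the list alone, camera adjusted p = 1.94e-15, adjusted p = 0.0113 with an estimated correlation). Of the glycolysis and hypoxia genes in MINI, 0 were higher and 9 lower of 24 tested (0 and 15 adjusted over the list alone, camera adjusted p = 2.98e-13, adjusted p = 0.193 with an estimated correlation), and in TID, 0 were higher and 15 lower of 24 tested (0 and 17 adjusted over the list alone, camera adjusted p = 1.3e-13, adjusted p = 0.197 with an estimated correlation), with enolase Eno1 at -0.48 ± 0.07 and -0.52 ± 0.07. Of the cholesterol synthesis genes in TID, 0 were higher and 10 lower of 20 tested. With 0 and 13 adjusted over the list alone, camera gave adjusted p = 3.32e-10, and adjusted p = 0.167 with an estimated correlation. In all, 731 genes changed in MINI (431 higher, 300 lower), 426 without EV replicate 1, 323 without EV replicate 2, 367 without MINI replicate 1 and 307 without MINI replicate 2. In TID, 1179 changed (673 higher, 506 lower), 551 without EV replicate 2, 520 without TID replicate 1 and 745 without TID replicate 2.

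Each fusion was compared with the response of WT over the 1802 genes changed in WT against EV. The fold change against EV had the sign of WT in 97.9% of these genes in FT, 96.7% in LOV, 80% in APEX, 82.2% in ULTRA, 62.2% in MINI and 59.9% in TID. An unchanged group would not give an even split, since EV stands in both fold changes. In 20 simulated draws with WT at its own levels and the fusions at those of EV, the share averaged 63.4% (61.2% to 66.8%) over the 2267 to 2519 genes called in the simulated WT, a larger set than the 1802, and the shares of MINI and TID lay below that average. Across all genes tested, the log2 fold changes of fusion and WT correlated with Pearson's r of 0.758 in FT (Spearman's rho 0.687), 0.725 in LOV (0.641), 0.447 in APEX (0.422), 0.477 in ULTRA (0.446), 0.232 in MINI (0.234) and 0.262 in TID (0.232). Genes are not independent replicates, and the EV libraries stand in both fold changes: in 20 simulated draws of unchanged groups against the same EV libraries, r averaged 0.509 (0.437 to 0.597) and rho 0.449. The covariance, to which shared controls add the same amount with or without an effect, was 0.496 in FT, 0.445 in LOV, 0.226 in APEX, 0.269 in ULTRA, 0.121 in MINI and 0.147 in TID, against 0.0934 in the simulation. With no filter r was 0.435 in MINI and 0.423 in TID. Without EV replicate 1 it was 0.488 in MINI and 0.496 in TID, and without EV replicate 2 it was 0.494 and 0.489. The simulation held both EV libraries and only genes past the filter. These higher values therefore have no simulated value beside them and do not show a stronger shared response. With WT set against EV replicate 1 and the fusion against EV replicate 2, so that no library stood in both, r was 0.439 in FT, 0.399 in LOV, 0.158 in APEX, 0.208 in ULTRA, 0.00383 in MINI and 0.0309 in TID. With the EV libraries exchanged it was 0.439, 0.398, 0.139, 0.182, 0.00359 and 0.0356. The share with the sign of WT was then 93.8% and 93.6% in FT, 91.4% and 92.8% in LOV, 72.3% and 70.3% in APEX, 76% and 74.1% in ULTRA, 53.7% and 53.8% in MINI and 52.1% and 55.5% in TID.

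Genes called in both a fusion and WT against EV were counted by direction. In FT 574 genes were higher in both, 591 lower in both and 4 opposite, and in LOV 447, 427 and 0, by edgeR's test. In APEX the numbers were 77, 49 and 9, in ULTRA 272, 232 and 37, in MINI 114, 74 and 107, and in TID 152, 118 and 164. EV stands in both lists, so that the overlap of independent lists was taken only with WT against EV replicate 1 and the fusion against EV replicate 2. In FT 305 were then higher in both (26.9 for independent lists), 333 lower in both (32.1) and 1 opposite (58.8), and in LOV 254 (21.8), 228 (21.7) and 0 (43.7). APEX gave 45 (4.37), 21 (2.06) and 10 (6.59), and ULTRA 130 (16.1), 119 (14.3) and 25 (30.5). MINI gave 49 (11), 20 (7.95) and 52 (19.2), and TID 68 (19.9), 45 (15.6) and 86 (35.9), above independent lists for genes of opposite direction as well. The number for independent lists gives every gene the same chance of a call, so that an excess over it alone does not show a shared response. With the EV libraries exchanged, MINI gave 39 (8.63), 22 (7.18) and 60 (15.9), and TID 63 (15), 40 (12.6) and 90 (27.9).

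**Figure D5:**
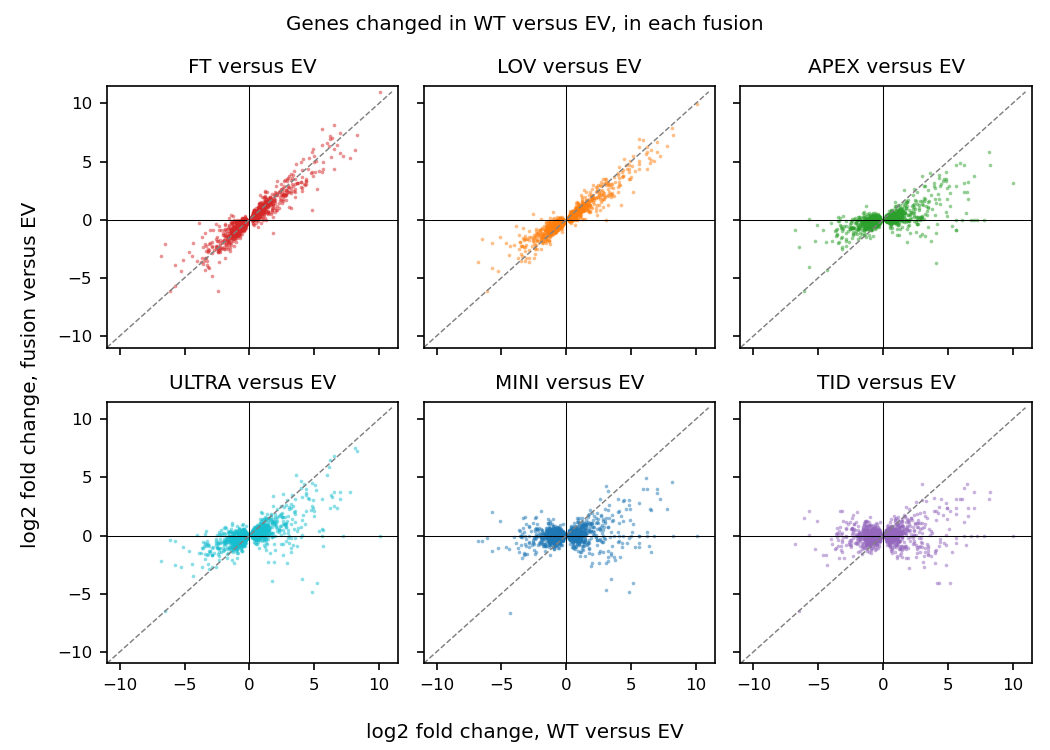
Each point is 1 of the 1802 genes changed in WT against EV, with its log2 fold change in WT (x axis) and in a fusion (y axis), both against EV, in a panel for each fusion, with equal change on the dashed line. FT and LOV have the sign of WT in 97.9% and 96.7% of the genes, MINI and TID in 62.2% and 59.9%.

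FT against the mean of the other 5 fusions sets the short peptide tag against the larger fusions, a contrast chosen here. LOV stands in that mean, but FT differed from it in 164 genes, against 1362 for APEX, 1453 for ULTRA, 2083 for MINI and 2260 for TID. The contrast therefore reflects mainly these last fusions and does not set FT apart from every larger fusion. Hspb1 was higher in FT (4.85 ± 0.15, adjusted p = 4.38e-17), as were Pram1, Cdc20b, the transcription factor gene Tcf24, Yap1 and Filip1, at 15.7 ± 0.503, 12.7 ± 0.457, 5.07 ± 1.47, 9.15 ± 1.37 and 5.28 ± 0.991 CPM. No fold is given for the last 5, which had 6 or fewer counts in at least 1 of the other fusions. Cd6 (-3.02 ± 0.25), Cxcr3 (-2.83 ± 0.14, adjusted p = 9.35e-15), Cd5 (-2.56 ± 0.26), Ctnnd2, delta-catenin (-2.42), Tmem154 (-2.34) and Cd226 (-2.33) were lower. Of the cytotoxic granule genes, 13 were higher and 2 lower of 21 tested (14 and 2 adjusted over the list alone, camera adjusted p = 2.28e-13, adjusted p = 0.0334 with an estimated correlation), and of the genes that Runx3 is known to activate, 10 were higher and 2 lower of 20 tested (11 and 2 adjusted over the list alone, camera adjusted p = 5.38e-08, adjusted p = 0.0334 with an estimated correlation). Of the cholesterol synthesis genes, 13 were higher and 0 lower of 20 tested (17 and 0 adjusted over the list alone, camera adjusted p = 3.4e-12, adjusted p = 0.0521 with an estimated correlation), and of the glycolysis and hypoxia genes, 13 were higher and 0 lower of 24 tested (15 and 0 adjusted over the list alone, camera adjusted p = 5.14e-09, adjusted p = 0.205 with an estimated correlation). In all, 1916 genes differed by edgeR's test, 990 higher and 926 lower, 1083 without FT replicate 1 and 1066 without FT replicate 2.

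Among the 6 fusions, Gzma separated the groups most clearly (adjusted p = 8.26e-26), at 6958 ± 309 CPM in FT, 4428 ± 14 in LOV, 1602 ± 107 in APEX, 1034 ± 40.6 in MINI, 853 ± 61.6 in TID and 645 ± 23.2 in ULTRA. Ass1, an enzyme of arginine synthesis, ran from 12.1 ± 1.46 CPM in FT and 15.1 ± 0.052 in LOV to 67 ± 4.59 in MINI and 80.6 ± 3.63 in TID (adjusted p = 1.12e-17). The inhibitory receptor genes Havcr2, or TIM-3, and Lag3 stood at 57.6 ± 2.24 and 82.1 ± 9.06 CPM in FT and at 10.7 ± 1.29 and 18.4 ± 1.2 in TID (adjusted p = 1.8e-15 and 9.86e-15). Cxcr3, Hspb1, the actin regulator Enah, the lysosomal protease Ctsd, the methyltransferase Hemk1 and the riboflavin kinase Rfk completed the 10 genes with the smallest p. In all, 3060 of 12894 genes differed among the fusions by edgeR's test.

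Between pairs of fusions, FT and LOV differed in 164 genes by edgeR's test. That number was 81 without FT replicate 1, 32 without FT replicate 2, 49 without LOV replicate 1, 66 without LOV replicate 2 and 318 with no filter. APEX and ULTRA differed in 435 genes, and in 181 without APEX replicate 1, 280 without APEX replicate 2, 216 without ULTRA replicate 1 and 282 without ULTRA replicate 2. FT differed from MINI in 2083 genes (1370 without FT replicate 2, 1380 without MINI replicate 1, 1382 without MINI replicate 2) and from TID in 2260 genes (1492 without FT replicate 2, 1474 without TID replicate 1). Between MINI and TID edgeR's test called 0 genes, with 638 of 12894 at an unadjusted p below 0.05, and DESeq2 called 2, edgeR with no filter 12 and edgeR with a replicate block 2, and edgeR called 1 without MINI replicate 2 or TID replicate 1. Gzma stood at 1034 ± 40.6 and 853 ± 61.6 CPM and Cxcr3 at 54.1 ± 4.16 and 54.3 ± 0.903 CPM in MINI and TID.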

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

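The counts between pairs of fusions and the fit without immunoglobulin genes were chosen after the data were seen. With 1 library left out, the number of changed genes fell in every comparison with EV or WT, where the group left with 1 library gives less power. It was 1061 to 1309 for WT against EV. Against WT it was 54 to 90 for FT, 13 to 134 for LOV, 709 to 826 for APEX, 768 to 929 for ULTRA, 1512 to 1757 for MINI and 1692 to 1873 for TID. Against EV it was 1078 to 1311 for FT, 583 to 985 for LOV, 91 to 140 for APEX, 565 to 657 for ULTRA, 307 to 426 for MINI and 520 to 806 for TID. For FT against the other fusions it was 1066 to 1938. With no filter, the count was 288 for FT against WT, 366 for LOV against WT and 320 for APEX against EV, and the cause was not tested. Runx3 in APEX against EV passed with no filter (-0.25), with the replicate block (-0.24) and with DESeq2 (-0.25). In MINI against EV it missed the threshold with only these libraries fitted (-0.24) and ranged from -0.32 to -0.18 with 1 library left out. The lists past camera's test numbered 6 with an estimated correlation for WT against EV. Against WT they numbered 0 for FT, 1 for LOV, 6 for APEX, 1 for ULTRA, 4 for MINI and 8 for TID. Against EV they numbered 4 for FT, 6 for LOV, 1 for APEX, 2 for ULTRA, 1 for MINI and 1 for TID, and 2 for FT against the other fusions. With the preset correlation, 7 lists passed for MINI against EV, and 7 to 11 with 1 library left out. Of 186 calls of lists, an estimated correlation ended 143 and the replicate block 2, and leaving out a library ended 70 calls, counted once per library, and reversed 1. The glycolysis and hypoxia list in APEX against EV changed direction without APEX replicate 2 (adjusted p = 0.266), with adjusted p-values of 4.63e-10 to 0.272 over the libraries left out. Across genes, the correlation with the WT response was 0.545 for FT, 0.542 for LOV, 0.435 for MINI and 0.423 for TID with no filter. With 1 library left out it was 0.574 to 0.776 for FT, 0.55 to 0.771 for LOV, 0.328 to 0.617 for APEX, 0.349 to 0.622 for ULTRA, 0.179 to 0.494 for MINI and 0.183 to 0.496 for TID. Unchanged groups were not simulated for these fits. Over all comparisons, 2163 fold changes were followed, those of the named genes and of every called member of the lists. Losses with a library left out are counted once per library left out, so that 1 fold change can count several times. DESeq2 ended 97 calls and added 10, and the fit of only the groups compared ended 153 and added 15. No filter ended 45 and added 22, the replicate block ended 6 and added 5, and the strict filter ended 1 and added 2. DESeq2 size factors ended 7, and leaving out a library ended 2487 and added 17. The correlation of same-numbered deviations lay between -0.066 and 0.094 over 28 pairs of groups. It was negative in every pair with MINI and positive in every other pair. Whether the replicate numbers pair the samples therefore stays open, and any shared effect was weak. With the replicate block the count rose in every comparison with EV or WT, to 1922 for WT against EV and 212 for FT against WT. No count against EV or WT moved by more than 1.5 times with the block. Without immunoglobulin genes, which was not run for the pairs of fusions, the other 15 counts stayed within 1.5 times. That fit tested 12889 genes in place of 12894, too small a change to move the counts further. It does not test whether B-lineage cells add to the differences through other genes.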

Other observations

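The tests of Runx3 and of a mix of cells were chosen after the result was seen, and those of MINI and TID after the count of 0 but before their own values. Against EV, 20 genes were higher in all 7 constructs and 8 were lower, a set chosen after the values were seen. The chemokine gene Ccl3, with 4 counts in EV, was 30.8-fold higher in WT by counts (interval 11.7 to 115) and 7.57-fold to 27.3-fold in the fusions, and Ccl4 was higher by 2.42 on the log2 scale in WT and 1.08 to 2.60 in the fusions. Kcnh2, a potassium channel, rose by 1.76 to 2.89, Zbp1, a sensor of nucleic acids, by 0.83 to 1.26, the actin-binding genes Zyx and Tmsb4x by 0.49 to 1.07 and 0.40 to 0.65, and Prdx1, a peroxidase that removes hydrogen peroxide, by 0.23 to 0.72. Igfbp4 changed by -3.38 in WT and by -0.92 in ULTRA, Ckb, a creatine kinase, by -2.06 in WT and -0.65 in TID, and Gusb, the lysosomal enzyme beta-glucuronidase, by -1.39 in WT and -0.47 in MINI. Another 3 genes were higher in all 6 fusions and not called in WT by edgeR's test. EV enters all of these comparisons, so that chance values in its 2 libraries count in each.

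Among gene groups outside the report, type I interferon genes were higher in LOV than in EV. Of these, 9 were higher and 0 lower of 23 tested, with Ifit1, an antiviral protein, at 2.13 ± 0.33 and Zbp1 at 1.103 ± 0.18. With 11 and 0 adjusted over the list alone, camera gave adjusted p = 2.08e-07, and adjusted p = 0.138 with an estimated correlation. Of the genes of resident T cells in tissue, 9 were higher and 1 lower of 32 tested in ULTRA against EV, with Xcl1 at 2.96 ± 0.27 and Hpgds, a prostaglandin synthase, at 3.53 ± 0.44. With 12 and 3 adjusted over the list alone, camera gave adjusted p = 0.00058, and adjusted p = 0.0673 with an estimated correlation. Of the p53 and DNA damage genes, 4 were higher and 0 lower of 20 tested in TID against EV, with the cell cycle inhibitor Cdkn1a at 0.55 ± 0.08 and Ccng1 at 0.39 ± 0.07. With 4 and 0 adjusted over the list alone, camera gave adjusted p = 0.000928, and adjusted p = 0.257 with an estimated correlation. Genes of biotin metabolism were read because 3 of the fusions carry a biotin ligase. Against EV, edgeR called 0 of 9 in ULTRA, MINI and TID, with camera adjusted p = 0.131, 0.973 and 0.632. Against WT, the list passed in ULTRA (adjusted p = 0.0437, and adjusted p = 0.122 with an estimated correlation), and lost the call without WT replicate 1 (0.0555), WT replicate 2 (0.0733) or ULTRA replicate 1 (0.12).

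Runx3 differed between WT and EV by -0.0745 on the log2 scale while 1802 genes changed. A construct that lacks the part of the gene that is counted, or that differs from it in sequence, may leave its reads out of the Runx3 count, which stays open, since the value is the observation itself and the sequence of the construct is not given in the sources used here. A low share of responding cells was tested from genes that fell, since a gene cannot fall by more than the responding share if the other cells keep their level and cells hold equal RNA. By a test against that size, 70 genes fell in WT by more than 1 on the log2 scale. This argues against a share of under 50%, as far as the groups held the same cell types. Markers of other lymphocytes, such as Ighm and Tcrg-C1, also fell in WT, and such genes were not set apart in that test. Lower endogenous Runx3 beside expression from the construct stays open.

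APEX and ULTRA lay between EV and WT on the first principal component, and a mix of EV-like and WT-like cells would put every gene between the levels of EV and WT. Of the genes called in APEX against EV, 24.48% were also called on the same side of WT, that is beyond the range of EV and WT, and in ULTRA 27.75%. These were 47 and 295 genes, while 39 and 76 were called between EV and WT, against 12 in FT, 35 in LOV, 39 in MINI and 44 in TID. The share was 4.12% in FT, 2.20% in LOV, 56.6% in MINI and 56.1% in TID. It depends on the number of genes called against EV, which was 1795 in FT, 192 in APEX and 1063 in ULTRA. By number, 74 genes lay beyond the range in FT and 27 in LOV. The 47 genes in APEX cannot decide on a mix, since FT, which differed from WT in few genes, gave more. The 295 genes in ULTRA argue against such a mix as the whole cause there. A lower activity or level of the fusion proteins, which were not measured in the data used here, is another hypothesis. If it only weakened the effect of WT, it would also keep genes between EV and WT. In ULTRA the 295 genes beyond the range then argue against it as the whole cause, and it stays open as a part. In APEX it stays open, since the 47 genes do not exceed the 74 in FT.

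MINI and TID differed in 0 genes by edgeR's test, with 638 at an unadjusted p below 0.05 and 2 genes by DESeq2. If 1 library of each carried the other's label, another split of the 4 libraries would separate them, provided that MINI and TID differ. The other splits called at most 0 genes, which argues against a swap that hid a difference large enough to be called. A swap between groups that do not differ would leave no trace in these splits and cannot be tested by them. Of all genes, 4.948% had an unadjusted p below 0.05, and 4.37% and 5.02% in the other splits, which is consistent with draws of 1 population. The spread among 2 libraries per group leaves small differences between these ligase fusions open.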
